A study of Mus musculus with 2 samples.

How the data were processed

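Total RNA was measured by sequencing in gastrocnemius from 2 female B6CASTF1/J mice, 1 library per animal, from 300 ng of RNA with ribosomal RNA reduced, a strand-specific kit and ERCC spike-ins, per the labels. Animals 1 and 3 of the labels are replicates 1 and 2. The labels give both the same donor identifier but separate tissue samples, and they were counted as 2 animals.

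The authors deposited, for each library, a gene table and a transcript table laid out as RSEM writes them and a transcript table laid out as kallisto writes them. Genome mm10 and annotation GENCODE M21 are named in the deposited descriptions, which also say that the first 2 came from transcriptome alignments and the last directly from reads; the programs and their versions are not given in the sources used here. The deposited expected counts are estimated reads per gene or transcript, not normalized, in which a read that fits several genes is shared out. The deposited TPM values are expected counts divided by effective length and scaled to 1 fixed total per library over all features, spike-ins included, so a few abundant short RNAs lower every other TPM value. The percent values deposited in the transcript table give each transcript's share of its gene. The deposited credibility bounds of TPM were read but not used in a test. The allele of origin of reads in these hybrids, and signal tracks, were not analysed here.

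All 55536 gene identifiers of the tables were found in GENCODE M21 (GRCm38, the assembly also called mm10), from which symbols, gene classes and coordinates came. Where a symbol names several genes, the one with the most counts was used. Features with numeric identifiers (1 count in all over both libraries), ERCC spike-ins and the phiX control were kept out of gene lists and gene counts. Transcript values of the second quantification were summed to genes.

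Expected counts were rounded to whole numbers for edgeR 4.0.16 in R 4.3.3. Library sizes were scaled by TMM, and log2 ratios of replicate 2 over replicate 1 were taken from CPM with a prior count of 2. Genes with a mean expected count of at least 50 entered comparisons between animals. A gene was called detected at 1 TPM or more in both animals. The biological coefficient of variation was estimated with an intercept-only design. With 2 animals in a single group no test between groups exists, so no p-value was computed; values are given as mean ± SD, and differences between animals are described by size. For each of 33 gene lists the summed and median TPM were computed, and for lists with at least 5 tested genes the median log2 ratio was placed among 10000 random lists, each member replaced by 1 of the 200 genes nearest in mean expression. Spike-in spread was placed among random sets in the same way. The gene lists, the rule for named genes and all alternatives except the removal of genes with shared reads were chosen before the data were examined; the second nerve and fasting lists and the grouping of clock genes by phase were chosen after.

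The genes named are the 4 highest members by mean TPM of each list, all members of 3 lists (myosin heavy chains, mitochondrial proteins, X and Y linked genes), the 20 highest nuclear protein-coding genes, the 10 highest other nuclear genes, the 10 largest log2 ratios in each direction, the listed isoform genes, and the 10 genes on which the quantifications differed most. Genes named outside that rule, such as Sln, Pax7, Chrng, Igf2, Ucp3, Fos and Egr1, were chosen after their values were seen. Some genes that the rule takes are not reported. A gene was said to share reads where the posterior SD of its count exceeded 5% of its mean in either animal. Some identical copies with equal counts, such as Rn7s1 and Rn7s2, escaped that criterion, while others, such as Rnu3b2 and Rnu3b3, met it.

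The steps were tested on simulated data. With counts drawn at the real means of 11125 genes and a coefficient of variation of 0.1, 99% of 200 genes changed 4-fold passed 2-fold in the right direction, and 2 unchanged genes did. The real common coefficient was 0.124, with values up to 0.215 at some abundances, and the simulation held no shared reads. Its count of 2 therefore does not carry over to the real genes. Simulated coefficients of 0.1 and 0.3 came back as 0.101 and 0.296. Of 200 simulated lists of 10 genes, 4% of unchanged lists and 96% of lists shifted by 0.5 lay outside the central 95%. These values were drawn independently for each gene, so the rates do not cover lists whose genes vary together or shifts below 0.5. Alternatives tried were DESeq2 1.42.0 size factors, spike-in scaling, a prior count of 0.5, count minimums of 10, other TPM thresholds, posterior mean TPM, the second quantification, rescaling over nuclear protein-coding genes and leaving out each animal. Tables were handled with Python 3.11.15, pandas 2.3.3, NumPy 2.4.6 and SciPy 1.17.1.

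No paired analysis was possible because there is only 1 group.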

Results

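Total RNA was sequenced from the gastrocnemius, the large muscle of the calf, of 2 adult female mice aged 8 to 10 months. Both animals were B6CASTF1/J, first-generation hybrids of the B6 and CAST strains. They form a single group, so no comparison between groups could be made and no p-value is given. The question addressed is descriptive: which transcripts the muscle held, at what level, and how far the animals differed. Replicate 1 held 42714567 expected counts and replicate 2 held 43421652. A gene with a count of 0 could still have had up to 3 counts, or a CPM of 0.0702 in replicate 1 and 0.0691 in replicate 2. Floors of this kind cover counting error only, since reads were counted without molecular identifiers. Counts of the 2 libraries differed by far more than sampling noise (chi-square per degree of freedom 29.2 over 11125 genes), which separate preparations of 1 animal could also show; that they are 2 animals rests on the labels. Errors are standard deviations over the 2 animals (n = 2), and levels are in TPM, a unit of transcript abundance scaled for length and depth. The abundant RNA genes Rn7s1 and Rn7s2 took 27.0% of TPM in replicate 1 and 33.6% in replicate 2, and protein-coding genes 48.2% and 43.3%. The SDs of TPM hold this shift as well as any difference of the gene itself. The log2 ratios given further below were scaled by TMM instead, so genes with close TPM values can still differ there.

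The most abundant protein-coding transcripts were those of the contractile apparatus and of energy supply in fast muscle fibres. Acta1, which encodes skeletal muscle alpha-actin, led with 21834 ± 2514 TPM (SD, n = 2), followed by Ckm, the muscle creatine kinase, with 19827 ± 1788 TPM. Fast troponin T (Tnnt3, 14673 ± 882 TPM), the fast regulatory light chain Mylpf (14169 ± 942 TPM) and the glycolytic aldolase Aldoa (13982 ± 1223 TPM) came next. In these libraries 10529 genes reached 1 TPM in both animals, of which 9673 were protein-coding, and 873 more reached it in 1 animal only. The 20 most abundant nuclear protein-coding genes held 39.6 ± 0.501% of all protein-coding TPM. Ttn, the giant spring protein of the sarcomere, ranked lower by TPM (4140 ± 643) but took 15.5 ± 1.29% of all expected counts because its transcripts are so long. In mm10 coordinates Acta1 (ENSMUSG00000031972.5) lies on chromosome 8 from 123891769 to 123894751, on the minus strand. Ttn (ENSMUSG00000051747.14) lies on chromosome 2 from 76703980 to 76982547.

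Myosin heavy chain transcripts, which mark fibre types, were dominated by the fastest isoform. Myh4 (type IIb) made up 85.9 ± 1.13% of the summed myosin heavy chain TPM, Myh1 (type IIx) 7.02 ± 0.803%, Myh2 (type IIa) 3.90 ± 0.187% and the slow isoform Myh7 2.24 ± 0.131%. This order was the same in both animals, and each step exceeded the standard deviations. Myh4 stood at 12243 ± 1137 TPM, 12.3 ± 1.57 times Myh1 and 38.4 ± 2.74 times Myh7. The perinatal isoform Myh8 reached 58.6 ± 5.73 TPM (102 TPM by the second quantification) and the embryonic isoform Myh3 2.05 ± 0.212 TPM. Myh13 and Myh7b lay at 1.39 ± 0.0283 and 1.04 ± 0.184 TPM. Myh15 had counts of 0 and 1. Myh6, the cardiac alpha isoform, was listed at 54.5 ± 1.91 TPM in this quantification, but the second quantification gave it a share of 0.186% against 0.383% here. The genes Myh2, Myh1 and Myh4 lie side by side on chromosome 11, Myh4 (ENSMUSG00000057003.12) from 67238029 to 67260446. By the second quantification Myh4 exceeded Myh1 8.99-fold, less than by the first.

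**Figure D1:**
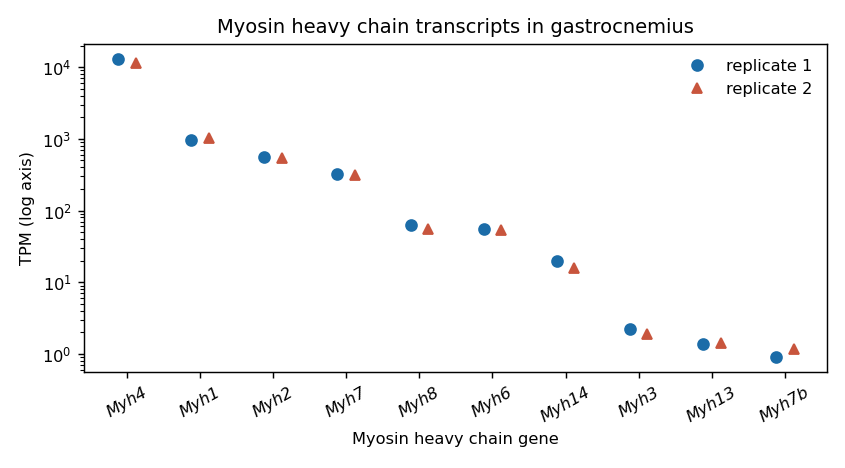
TPM of 10 myosin heavy chain genes (log axis) in replicate 1 (circles) and replicate 2 (triangles), 1 point per animal; Myh15, at 0 TPM, is not drawn. Myh4 lies highest in both animals (mean 12243 TPM), followed by Myh1 (996 TPM).

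Fast fibre genes, with myosins among them, also stood above slow fibre genes as lists. All 14 fast fibre genes were detected and summed to 95604 ± 8209 TPM, with parvalbumin (Pvalb, 7093 ± 747 TPM), a calcium buffer of fast fibres, and Actn3 (4502 ± 597 TPM), the fast alpha-actinin, among them. Of the 14 slow fibre genes 13 were detected, and the list summed to 2305 ± 74.1 TPM, led by the slow light chains Myl2 (420 ± 2.62 TPM) and Myl3 (336 ± 24.8 TPM). Glycolysis and glycogen genes summed to 36222 ± 2744 TPM, with Gapdh at 6178 ± 481, Eno3 at 3921 ± 129 and glycogen phosphorylase Pygm at 3788 ± 300 TPM. The 18 nuclear respiratory chain genes summed to 7694 ± 323 TPM, led by Atp5b (1678 ± 84.4) and Cox8b (783 ± 31.8). Excitation-contraction coupling genes were led by the calcium release channel Ryr1 (1003 ± 131 TPM), and sarcolipin (Sln), a regulator of the calcium pump, had only 5 and 14 counts. Among muscle transcription regulators all 14 were detected, Mef2c highest at 188 ± 17.8 TPM. Developmental muscle genes were led by cardiac actin Actc1 (72.2 ± 14.2 TPM) by the first quantification. By the second they were led by Myh8, with 102 of 182 summed TPM. Chrng, the fetal acetylcholine receptor subunit, had 1 and 2 counts.

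Transcripts of cells other than muscle fibres were present at much lower levels. Fibroblast genes, all 11 detected, summed to 302 ± 56.5 TPM, led by Gsn (126 ± 17.4) and the proteoglycan Dcn (67.2 ± 14.8). All 10 endothelial genes were detected, summing to 76.5 ± 12.8 TPM, with Egfl7 at 14.3 ± 0.325 and Cdh5 at 12.2 ± 1.96 TPM. Smooth muscle and pericyte genes summed to 169 ± 27.2 TPM, of which Abcc9 (63.9 ± 9.48 TPM), also a potassium channel subunit of muscle fibres, and Rgs5 (59.4 ± 13.7 TPM) made up most. Satellite cell genes were led by Itga7 (25.1 ± 1.45 TPM), which muscle fibres also express, while Pax7, the stem cell marker, lay at 0.405 ± 0.00707 TPM. Schwann cell and nerve genes summed to 57.3 TPM in replicate 1 and 12.7 in replicate 2, with 3 of 8 detected. Of the macrophage genes 4 of 9 were detected, Csf1r highest at 1.90 ± 0.0354 TPM. Haemoglobin genes Hbb-bs and Hba-a1 lay at 72.7 ± 15.5 and 57.9 ± 12.2 TPM. Ighm was the only detected gene of the lymphocyte and neutrophil list, at 52.8 ± 36.0 TPM. Tendon genes were led by Thbs4 (14.0 ± 4.04 TPM) and adipocyte genes by Fabp4 (49.2 ± 9.44 TPM), which endothelial cells also express. Among 13 genes of heart, liver, brain and skin only Myh6 and Krt10 were detected, Krt10 at 1.39 ± 0.0849 TPM.

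Genes of stress, signalling and daily rhythm spanned a wide range. Heat shock genes, all 10 detected, summed to 1880 ± 202 TPM, led by the small chaperone Cryab (590 ± 28.2) and by Hspb6 and Hspa8 (504 ± 79.0). Of the 14 atrophy and glucocorticoid genes all were detected, summing to 515 ± 122 TPM, led by Tsc22d3 (180 ± 70.5 TPM), a target of the glucocorticoid receptor. Clock genes summed to 321 ± 18.4 TPM, 14 of 15 detected, with Tef at 97.4 ± 4.05 and Dbp at 59.9 ± 16.4 TPM. Immediate early genes summed to 121 ± 4.84 TPM and myokines to 203 ± 37.1 TPM. The 11 neuromuscular junction genes summed to 67.9 ± 0.601 TPM, 10 of them detected. Of the 9 interferon response genes 3 were detected.

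Sex-linked genes were those of females. Xist, the RNA that coats the inactive X chromosome, had 3260 and 3946 counts (8.41 ± 1.15 TPM). The Y-linked genes Kdm5d, Uty and Eif2s3y had 0 counts in both libraries and Ddx3y had 1 in each. Imprinted genes were led by H19, a non-coding RNA expressed from the maternal allele, at 310 ± 31.7 TPM, whereas Igf2 from the same locus stood at 11.7 ± 0.891 TPM. Of the 18 imprinted genes 10 were detected, with Snrpn at 34.1 ± 2.06 TPM and Igf2r at 22.6 ± 0.219 TPM.

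Small structured RNAs took a large part of the TPM and a small part of the reads. The 7SL RNA genes Rn7s1 and Rn7s2, the RNA of the signal recognition particle, together held 30.3 ± 4.60% of TPM but 4.26 ± 1.00% of expected counts. Protein-coding genes held 45.8 ± 3.50% of TPM and 79.6 ± 1.28% of counts. The mitochondrial ribosomal RNAs held 10.4 ± 1.05% of TPM, and small structured RNA as a class 32.5 ± 5.12%. The 7SK RNA gene Rn7sk reached 6164 ± 28.6 TPM and the RNase P RNA gene Rpph1 2094 ± 250 TPM. Rn7s1 (chromosome 12, 69159295 to 69159594) and Rn7s2 carried identical counts, 758930 each in replicate 1, so the level of either copy alone is uncertain. ERCC spike-ins, synthetic RNAs added to each sample, held 0.512 ± 0.0133% of TPM.

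The 13 protein-coding genes of the mitochondrial genome were all detected and held 4.40 ± 0.242% of TPM. By the first quantification the highest were mt-Co1 (12949 ± 898 TPM), mt-Cytb (6394 ± 265 TPM) and mt-Nd1 (4762 ± 340 TPM), subunits of complexes IV, III and I. By contrast mt-Co2 was listed at 137 ± 40.7 TPM, mt-Co3 at 1268 ± 26.5 and mt-Atp6 at 2884 ± 627. Near-identical nuclear pseudogenes on chromosome 1 had high values, Gm28437 with 13649 ± 1006 TPM and Gm28661 with 12373 ± 541 TPM. They and 3 neighbours held 77.9 ± 0.0913% of all pseudogene TPM. The second quantification gave mt-Co2 1032 TPM, mt-Co3 5169 TPM and mt-Atp6 8508 TPM, so values of these genes and their copies are uncertain. It placed mt-Cytb at 5739, mt-Nd3 at 5540 and mt-Nd1 at 3837 TPM, with mt-Co1 highest again (12532 TPM). The order below mt-Co1 and the summed share of the 13 genes are thus uncertain too.

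Between the 2 animals, genes of myelin and Schwann cells were among those that differed most and had reads of their own. Mbp, a myelin protein, had 1093 and 241 counts and was 4.56-fold higher in replicate 1, and Spp1 (osteopontin) 8.17-fold, on counts of 95 and 10. In replicate 2 Cish, a target of STAT5 signalling, was 5.54-fold higher, with 55 and 317 counts. Of 11125 genes with a mean expected count of at least 50, 154 differed at least 2-fold, 76 higher in replicate 2 and 78 higher in replicate 1. With scaling to the spike-ins 55 were higher in replicate 2 and 128 in replicate 1, and the median of all genes moved from 0.00 to -0.12 on the log2 scale. Among the 154, 60 shared reads with near-identical copies, such as the pseudogene Gm14760 (8 and 1725 counts) and the histone gene Hist1h4n (114 and 0 counts). Those values are uncertain; of the 94 others 34 were higher in replicate 2 and 60 in replicate 1. Among the 20 genes with the largest ratios, Cish, Spp1, Cadm4 and Mbp did not share reads. The common biological coefficient of variation by edgeR was 0.124, and each animal has 1 library, so single genes have no replicate check.

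**Figure D2:**
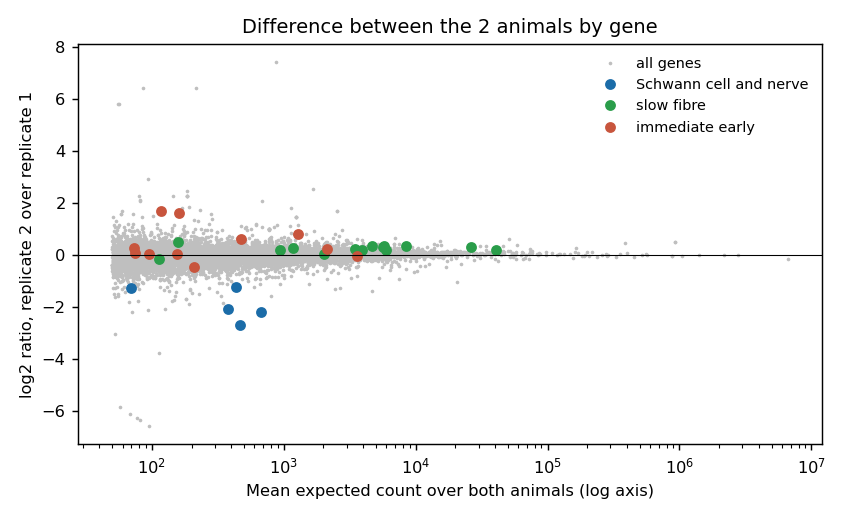
The log2 ratio of replicate 2 over replicate 1 against the mean expected count (log axis) for genes with a mean count of at least 50, 1 grey point per gene, with 3 gene lists in colour. The 5 Schwann cell and nerve genes lie well below 0 (median -2.10), the slow fibre genes mostly just above 0.

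As groups, nerve genes were lower and slow fibre genes higher in replicate 2. All 5 tested Schwann cell and nerve genes were at least 2-fold higher in replicate 1, with a median log2 ratio of -2.10, below all 10000 random lists matched on expression; Prx was 4.28-fold and Pmp22 2.37-fold higher. Of 14 slow fibre genes 13 were higher in replicate 2 (median 0.26, above all random lists; 0.13 with spike-in scaling), including Myl3 (0.33) and Tnnc1 (0.33). Fibroblast genes were lower in replicate 2 (9 of 11, median -0.25, percentile 0), as were endothelial genes (8 of 10, median -0.22, percentile 0.0700) and smooth muscle and pericyte genes (7 of 8, median -0.12, percentile 1.58). Heat shock genes were lower too (7 of 10, median -0.20, percentile 0.0100), with Hspa8 at -0.21, although Cryab was at 0.09 (-0.04 with spike-in scaling). Immediate early genes were higher in replicate 2 (9 of 11, median 0.21, percentile 99.8; 0.08 with spike-in scaling), with Dusp1 at 0.81 and Btg2 at 0.59. Circadian clock genes had a median of 0.18 (percentile 99.97; 0.05 with spike-in scaling), with Dbp at 0.73 and Tef at 0.01 (-0.12 with spike-in scaling). Myosin heavy chains had a median of 0.13 (percentile 99.2; 91.9 by the second quantification) and neuromuscular junction genes of 0.15 (percentile 99.0), which with spike-in scaling were 0.00350 and 0.02. Their percentiles there, among lists scaled alike, were 99.2 and 99.0. Structural non-coding RNAs had a median of 0.37 (0.25 with spike-in scaling), with 10 of 10 higher in replicate 2, counting the identical copies Rn7s1 and Rn7s2 separately. All 18 nuclear respiratory chain genes were higher in replicate 2, but their median of 0.10 turned to -0.03 with spike-in scaling, which shifts all genes; their percentile was 99.3 with either. The fast fibre median was -0.01 and turned to 0.01 with DESeq2 size factors. In total 13 of 28 tested lists lay outside the central 95% of random lists, against 1.40 expected for lists of unrelated genes. This describes these 2 libraries only, and genes of a list can vary together, while some lists share genes. Without genes with shared reads, an alternative added after seeing the data, 12 lists lay outside, as the fast fibre list moved from percentile 2.46 to 2.53.

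**Figure D3:**
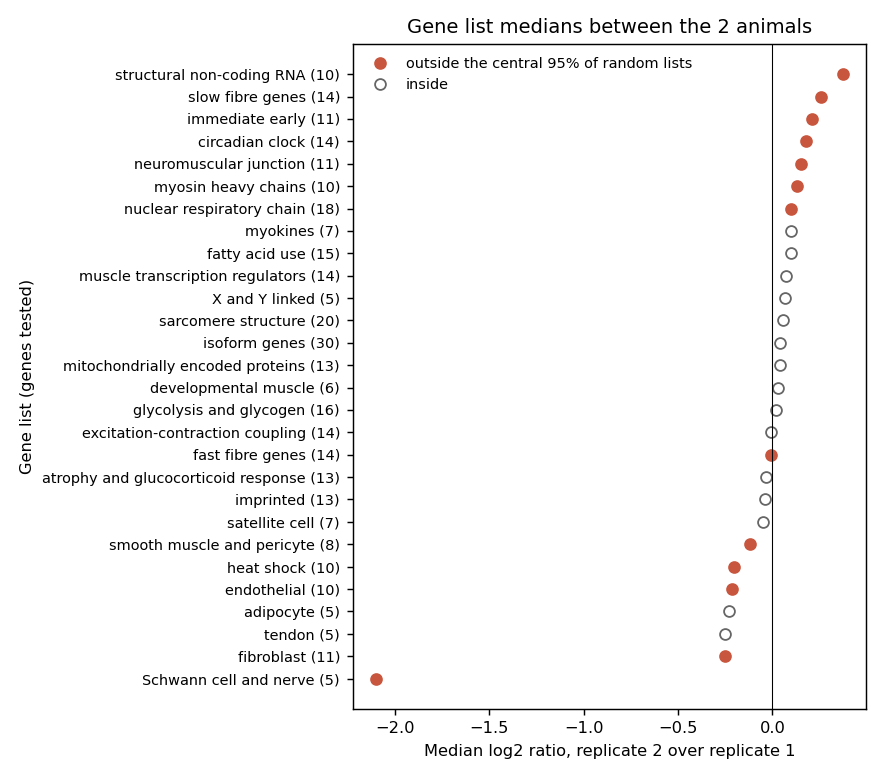
Median log2 ratio of replicate 2 over replicate 1 for 28 gene lists, with the number of genes tested in parentheses; filled points lie outside the central 95% of 10000 random lists matched on expression. The Schwann cell and nerve list stands apart at -2.10, while other lists lie between -0.25 and 0.37.

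The other 15 tested lists lay inside the central 95%, and single members differed within them. Their medians were 0.06 for sarcomere structure, -0.01 for excitation-contraction coupling, 0.02 for glycolysis and glycogen, 0.04 for mitochondrially encoded proteins, 0.03 for developmental muscle, -0.03 for atrophy and glucocorticoid response, -0.05 for satellite cells and 0.07 for muscle transcription regulators. They were 0.10 for myokines, -0.04 for imprinted genes, 0.07 for X and Y linked genes, 0.04 for isoform genes, -0.25 for tendon and -0.23 for adipocyte genes. With spike-in scaling all of these that lay above 0 turned negative and those below 0 remained so. Macrophage, erythroid, lymphocyte and neutrophil, interferon and other tissue genes had fewer than 5 members with enough counts. Fatty acid genes had a median of 0.10 (percentile 97.4; -0.03 with spike-in scaling), yet Pdk4, the kinase that turns off pyruvate oxidation, was 2.09-fold higher in replicate 1. Among atrophy and glucocorticoid genes Tsc22d3 was 1.58-fold higher in replicate 1, and the ubiquitin ligases Fbxo32 and Trim63 had log2 ratios of -0.47 and -0.28, while Mstn (myostatin) was at 0.41. Ighm was 2.52-fold higher in replicate 1, with 3489 and 1399 counts. The spike-ins, which carry no animal difference, spread less than genes of like abundance. The log2 ratios of 30 spike-ins had an SD of 0.17, lower than in all but 1.65% of matched random gene sets, whose median SD was 0.28. For 42 spike-ins with a mean count of at least 10 the SD was 0.33 at percentile 6.07, inside the central 95%.

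Dominant transcripts were mostly the same in both animals. Among 3768 multi-transcript genes of at least 10 TPM, 92.8% had the same most abundant transcript in both, and 73.5% had it in both animals and both quantifications. The median share of that transcript was 69.6%. Of 30 muscle genes with known isoforms, 22 kept 1 dominant transcript throughout. Atp2a1, the fast calcium pump, was almost wholly Atp2a1-201 (99.96%), and Ryr1 was 97.7 ± 0.0283% Ryr1-202. Tpm3 was 96.1 ± 0.686% Tpm3-205 and Bin1 80.7 ± 0.495% Bin1-205. The pyruvate kinase gene Pkm was 52.9 ± 0.728% Pkm-202, and Mbnl1, a splicing regulator, spread over 25 transcripts with 17.8 ± 0.311% in the highest. For Myl1, Fhl1, Tpm2, Tnnt1, Ttn, Mbnl1 and Pgm5 the dominant transcript differed between quantifications or animals, and in Myl1 it was Myl1-202 by the first (78.2 ± 0.106%) and Myl1-207 by the second (82.4%).

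The 2 quantifications of the same reads gave like values for most nuclear protein-coding genes and unlike ones for short RNAs and pseudogenes. Of 4692 genes with at least 10 TPM by either, 232 differed at least 2-fold in both animals. They included 40 of 4342 nuclear protein-coding genes (0.921%), 4 of the 13 mitochondrial ones, 7 of 58 lncRNAs (12.1%), 96 of 181 pseudogenes (53.0%) and 85 of 95 small structured RNAs (89.5%). Rmrp, the RNA of RNase MRP, stood at 666 ± 0.785 TPM by the first and 0 by the second for the copy on chromosome 4, and mt-Atp8 at 1460 ± 268 against 1.41 TPM. In the other direction the chromosome 1 pseudogene Gm28439 was listed at 0 by the first and 652 TPM by the second. Across genes, which are not independent replicates, Pearson's r of log2(TPM + 1) was 0.969 in replicate 1 and 0.966 in replicate 2 (Spearman's rho 0.904 and 0.898). Across transcripts it was 0.860 and 0.855 (rho 0.773 and 0.769).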

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

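Reads of phiX174, a bacteriophage genome commonly added to sequencing runs as a control, appeared outside the gene measurements. There were 76 in replicate 1 and 100 in replicate 2, above the 3 counts that a count of 0 allows. They made up 0.000178% and 0.000230% of expected counts, and no explanation for their level was tested. Groups of 2 animals are too small for a search for outlying samples.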

How the results depend on the processing

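The removal of genes with shared reads was chosen after seeing the data; all other alternatives were planned. No paired analysis was possible because there is only 1 group, and with 2 animals leaving out either moves a mean by less than 1 SD by construction. Main values moved as follows, and the cause was not tested unless the alternative itself makes the change. At 5 TPM 6372 genes were detected. As shares of expected counts, which are not divided by length, protein-coding genes held 79.6%, mitochondrial rRNA 8.92%, small structured RNA 4.48%, mitochondrial protein-coding genes 3.08%, pseudogenes 2.12%, lncRNA 1.53% and ERCC spike-ins 0.266%. By the second quantification small structured RNA held 39.2% of TPM, mitochondrial rRNA 8.52%, mitochondrial protein-coding genes 5.24%, pseudogenes 2.89% and spike-ins 0.435%. Shares of myosin heavy chain by that quantification were 83.0% for Myh4, 9.31% for Myh1 and 2.45% for Myh7, and from counts 87.2% for Myh4 and 1.64% for Myh7. Genes 2-fold apart between animals numbered 578 with a mean count of at least 10, where more genes are tested, 95 on log2(TPM + 1), which differs in both scaling and pseudocount, and 94 without genes with shared reads. By the second quantification, with the count minimum set on its own counts, they numbered 108 against 154 by the first. Only 76 genes passed 2-fold by both. The coefficient of variation was 0.134 at a mean count of 10 and 0.105 without genes with shared reads. The spike-in SD was 0.33 at a mean count of 10. Pearson's r between quantifications was 0.841 across transcripts and 0.964 across genes with a pseudocount of 0.1, and 0.670 and 0.899 for features of at least 1 TPM by either. For genes of at least 1 TPM 69.9% kept 1 dominant transcript, with a median share of 69.3%; by the second quantification the median share was 63.4%. Log2 ratios that turned by the second quantification were those of Chtf8 (-0.76), Gm2260 (0.17) and Gm2004 (0.37), all with shared reads. The medians of fast fibre genes (0.00783 with DESeq2 size factors) and nuclear respiratory chain genes (-0.0300 with spike-in scaling) turned too. The second quantification counted too few reads for 8 of the 20 named ratios, which have no value there. Rescaling over nuclear protein-coding genes moved the summed TPM of all 33 lists, and the second quantification that of 18. Depth limits genes with few counts, where 1 read is a large part of the value.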

Other observations

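Genes outside the naming rule, chosen after their values were seen, also differed between the animals. Immediate early genes Fos and Egr1 were 3.05-fold and 3.20-fold higher in replicate 2, and the cytokine-signalling inhibitors Socs2 and Socs3, like Cish, 2.95-fold and 2.97-fold. Dusp10, a phosphatase of stress-activated kinases, was 4.25-fold higher there. The endothelial transcription factor genes Sox18 and Sox7 were 3.70-fold and 3.24-fold higher in replicate 1. Ighm had 3489 and 1399 counts while Igkc, the light chain constant gene, had 2 and 1. Small nuclear RNA as a class, summed over copies so that reads shared between copies of the class do not matter, took 0.0261% of counts in replicate 1 and 0.0631% in replicate 2, and small nucleolar RNA 0.0117% and 0.0188%.

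For the patterns that follow, tests with predictions written before their results were seen are the second nerve list, the spike-in length test and the second fasting list; the other tests were chosen after. A test was taken to decide only where its value passed the written bound by more than its bootstrap standard error.

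Nerve genes were higher in replicate 1. Scaling for sequencing depth moves all genes alike, so it could not bring this list to the level of the others. With spike-in scaling the list median was -2.23 and that of all genes -0.12. The scaling factors fix that shift in advance, so it is no further test. Reads shared with near-identical copies are argued against, since the list median was -2.17 by the second quantification. More peripheral nerve in the piece of muscle from replicate 1 may be the source, but the second nerve list left this open, with a median of -0.65 over the 4 of 18 genes with a mean count of at least 50, between the bounds of -1 and -0.5; the highest of them, L1cam, stood at 1.17 TPM. With a minimum of 10, looked at after that result, 14 of 16 genes were lower in replicate 2 with a median of -1.30.

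Small structured RNA was higher in replicate 2, in 59 of 61 genes. Some of these are copies that split the same reads and have identical values, such as Rnu3b2 and Rnu3b3. The 61 are therefore not independent, and their bootstrap standard errors may be too small. Summed over copies, small nuclear RNA took 0.0261% of counts in replicate 1 and 0.0631% in replicate 2. A few abundant genes alone are argued against by the other 59 genes (median 0.98). The 37 small RNAs outside the shared-read criterion, which Rn7s1 and Rn7s2 escaped, had a median of 0.53. Scaling moves all genes alike, so it could not set these RNAs apart from other genes. With spike-in scaling their median was 0.83 and that of all genes -0.12, a shift fixed by the scaling factors and no further test. A library effect that favours short RNA could account for it and stays open. Short spike-ins lay -0.0107 from long ones (log2), past the bound written against this explanation, but that bound did not test it, since the shortest tested spike-in has 505 nt and 60 of the 61 RNAs are shorter. The second quantification had no reads for 46 of the 61, and gave a median of 0.43 over the 10 with enough.

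Single genes known to be raised by fasting, picked because of their values, were higher in replicate 1, Ucp3 2.60-fold, Pdk4 2.09-fold and Foxo1 1.89-fold. Scaling for sequencing depth moves all genes alike, so it could not set these genes apart from the others. The median of 6 such genes went from -0.83 to -0.96 with spike-in scaling, where that of all genes was -0.12. The scaling factors fix that shift, so it is no further test. As these 6 were chosen for their values, this says nothing on whether other such genes differed. A difference in feeding state might be thought of, but a second fasting list of 16 tested genes had a median of 0.0026 with 8 higher in each animal, so such genes as a group were not higher in replicate 1, which gives it no backing and does not exclude it. A difference in time of day is also open. The 10 clock genes in phase with Dbp lay 0.39 above the 3 out of phase. That was within its standard error of 0.30 of the bound of 0.3, and 3 genes are fewer than the 5 asked of a list.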
